A study of Homo sapiens with 8 samples.

How the data were processed

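The series measured RNA in NCI-H2009, an established human lung adenocarcinoma cell line that had been given dCas9-KRAB. This fusion joins a Cas9 that binds DNA without cutting it to the KRAB domain, which recruits chromatin repressors to the site that a guide RNA selects. The 8 libraries fell into 4 groups of 2. One group received no guide RNA, one a guide without a target in the human genome, and 2 groups each received a different guide to the same enhancer, called e3. Poly(A) RNA was selected before library preparation, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, and the columns of the table were matched to the samples by their names, with the design text giving the name used for the non-targeting guide.

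The deposited values were RPKM (reads normalized to gene model length and library depth), per the file headers, with 1 column per library and 52576 genes under versioned Ensembl identifiers and symbols. The genome build hg19 and the program Cufflinks are named per the submitters' processing notes, without a role or a version. The aligner, the counting of reads, the strand setting and the annotation release were not given in the sources used here. Gene symbols and identifiers are those of the deposited table. A GENCODE 29 annotation, which belongs to another build, was used only for gene type, chromosome, length and GC content, and no coordinates are given. Of the 13979 genes tested, 13432 had an entry there.

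RPKM carries no depth of its own, so the depth was inferred from the steps between low values. In each of the 13979 genes tested (100%), the values of the 8 libraries were whole multiples of the worth of 1 read, to within 0.03 reads. The inferred depths lay between 3875080 and 5754470 reads per library. At 1 RPKM a gene of the median length of 3.10 kb held 12 reads in the shallowest library and 17.8 in the deepest, and the median over tested genes and libraries was 122 reads. These reads served to judge precision and to equalize depth in a check. No count test was run on them, because the deposited unit was RPKM.

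Tests were run on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes moderated test with a variance trend, two-sided), for genes with a mean of at least 1 RPKM over the 8 libraries. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. Errors on log2 changes are standard errors, and errors on RPKM levels are SDs over the libraries given. The 4 libraries with an e3 guide were compared with the 4 control libraries in a model with 2 groups, so that its spread includes the differences between the guides and between the controls. Each guide alone, the guides against each other and the controls against each other were tested in a model with 4 groups. Comparisons of the e3 libraries with one control alone used the 6 libraries concerned. For MYC an exact two-sided permutation test over the 70 arrangements of the 8 libraries was added.

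Gene lists were tested with limma's camera, with a preset correlation of 0.01 between genes and again with a correlation estimated from the residuals, for the e3 guides against the controls and for the controls against each other. With an estimated correlation camera also falls back to the residual degrees of freedom of the model, 6 with 2 groups and 4 with 4 groups. Of 31 lists fixed before the data were examined, 29 had at least 5 genes tested. The designs, the lists, the rule for named genes and the alternatives to be tried were all fixed at that time. The rule named MYC and its neighbour PVT1, then the 12 largest rises and 12 largest falls among called genes whose 4 e3 libraries all lay on one side of the 4 control libraries. It named up to 5 genes per direction for each other comparison, up to 4 members of each list by smallest p, and any gene of the 8q24 list that passed in any comparison. Rows without a gene symbol and multigene families with near-identical copies were passed over, by a list of name patterns that did not include every paralog family. A few genes that the rule named are not reported here, though they were tested and count in every total.

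The gene tests of the e3 guides and of guide 1 against the controls, and of the controls against each other, were tried on simulated data with 200 changed genes among 13979. The list test with the preset correlation was tried on simulated lists, and the other steps were not tried in this way. For the e3 guides against the controls, 73 of 100 genes changed by 1 on the log2 scale and 29 of 100 changed by 0.5 were recovered, with 5 false calls. The simulated noise was independent between libraries, without differences between groups, so these false calls do not cover such differences. The alternatives tried were a pseudocount of 0.1, no filter and a minimum mean of 5 RPKM, median-ratio and quantile scaling, no variance trend, the replicate number as a block, a 4-group model, each control alone and each library left out. Alternatives added after seeing the data were group means as the samples, an estimated correlation between libraries of a group, and removal of each library's trend in GC content and length. Figures were drawn with matplotlib 3.10.9.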

Results

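RNA was sequenced from 8 libraries of NCI-H2009 cells carrying dCas9-KRAB, 2 without a guide RNA, 2 with a non-targeting guide, 2 with e3 guide 1 and 2 with e3 guide 2. The enhancer e3 is part of a cluster of enhancers on chromosome 8 downstream of MYC, a region amplified in some lung adenocarcinomas, and the comparison asks what its repression does to gene expression. Inferred depths were 4693343 and 4220240 reads without a guide, 4670714 and 4757909 with the non-targeting guide, 4358612 and 3875080 with guide 1, and 5754470 and 4287211 with guide 2. Between 18240 and 19508 genes were above 0 in a library. The first principal component held 38.9% of the variance and placed the no-guide libraries (-36.9 and -38.4) apart from the other 6 (5.74 to 18.5).

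The 2 libraries of a group were close. Over 11961 genes with at least 10 reads in every library, their chi-square per degree of freedom was 2.12 without a guide, 1.96 with the non-targeting guide, 1.91 with guide 1 and 1.99 with guide 2. Counting noise alone would give 1 if every read were independent, and 2 if both reads of a pair were counted, and how reads were counted was not given in the sources used here. Among genes with at least 3000 reads it was 5.36 without a guide, 3.79 with the non-targeting guide, 2.26 with guide 1 and 2.89 with guide 2, above both values. Between groups it ran from 3.12 to 19.8. The labels do not say that the libraries of a group came from separate cultures. The p-values of the model with 4 groups therefore measure the spread between these libraries, which may be technical. In the model with 2 groups the spread also includes differences between the guides and between the controls, though each library still counts as a sample.

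MYC (ENSG00000136997.9, chromosome 8), the transcription factor gene for which the enhancer is studied, was lower in every e3 library than in every control library. Its level was 74.6 and 72.7 RPKM without a guide and 88.9 and 90.1 RPKM with the non-targeting guide, against 42.4 and 43.4 RPKM with guide 1 and 36.3 and 36.2 RPKM with guide 2. The control mean of 81.6 ± 9.20 RPKM (SD, n = 4) compares with an e3 mean of 39.6 ± 3.87 RPKM (SD, n = 4). MYC fell by 1.02 ± 0.10 on the log2 scale, to 0.492 of the control level (limma, adjusted p = 0.00215). It fell by 0.91 with guide 1 (adjusted p = 4.31e-05) and by 1.14 with guide 2 (adjusted p = 9.34e-06). The exact permutation p was 0.0286, the smallest that 70 arrangements of single libraries can give. Keeping the libraries of a group together leaves 3 splits. With group means as samples the unadjusted p for MYC was 0.000551 (limma) and the adjusted p was 0.407. Genes with a larger unadjusted p, such as PADI3 (0.00486), had the same adjusted p there. Between 465 and 1284 reads lay behind each MYC value.

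Among the other genes of the 8q24 list, KCNQ3, a potassium channel gene, rose from 1.16 ± 0.22 to 2.77 ± 0.23 RPKM (SD, n = 4 each; log2 change 0.81, adjusted p = 0.0149). PVT1 (ENSG00000249859.2), the non-coding RNA gene next to MYC, had 2.01 ± 0.21 RPKM in the controls and 1.90 ± 0.35 RPKM with the e3 guides (log2 change -0.06 ± 0.14, adjusted p = 0.848). TRIB1 and MTSS1 did not pass, with log2 changes of 0.23 and 0.75. Of the 22 genes of the list that were tested, 1 was higher, 1 was lower and 20 did not pass, and the same 2 were called when adjusted over the list alone. The list as a whole did not stand apart from other genes (camera adjusted p = 0.751). MTSS1 passed with guide 2 alone (log2 change 1.03, adjusted p = 0.0204), and FAM84B with each guide (-0.21, adjusted p = 0.0487, and -0.27, adjusted p = 0.0144). FAM84B, NDUFB9 and WDYHV1 differed between the controls (non-targeting guide against no guide), by -0.92, 0.32 and 0.57. For FAM84B that difference put the non-targeting guide lower than either e3 guide. Its fall therefore holds against the mean of the controls but not against the non-targeting guide.

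**Figure D1:**
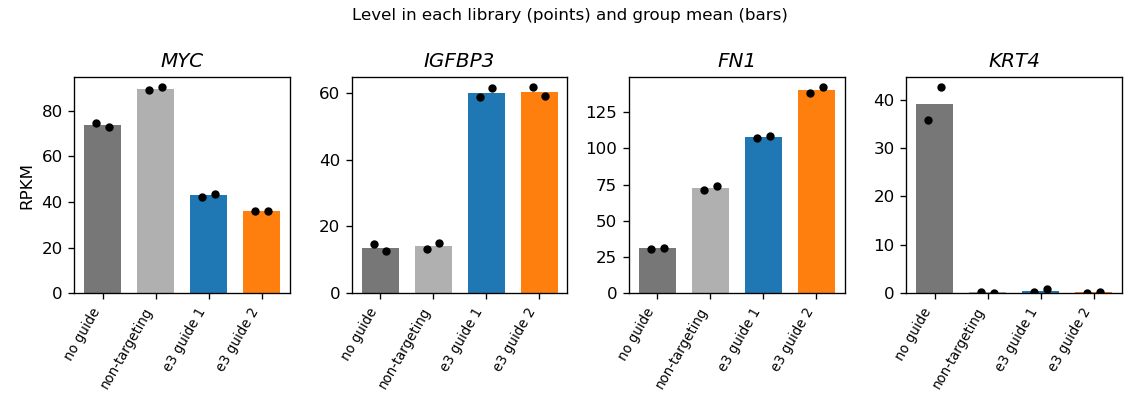
RPKM of MYC, IGFBP3, FN1 and KRT4 in each library; points are the 2 libraries of a group and bars their mean, and each panel has its own axis from 0. MYC lay between 36.2 and 43.4 RPKM in the 4 e3 libraries and between 72.7 and 90.1 RPKM in the 4 controls, whereas KRT4 separated the no-guide libraries from the other 6.

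IGFBP3, which encodes a binding protein for insulin-like growth factors, had the largest rise among the genes called between the e3 guides and the controls, from 13.9 ± 1.21 to 60.1 ± 1.49 RPKM (SD, n = 4 each; log2 change 2.04 ± 0.07, adjusted p = 2.31e-06). It stood at 58.7 and 61.3 RPKM in the libraries of guide 1, at 61.5 and 59.0 RPKM in those of guide 2, and at means of 13.7 and 14.1 RPKM in the controls. RRAD, a small GTPase gene (log2 change 1.90), ITGB6, an epithelial integrin subunit (1.77), and PMEPA1 (1.72) followed. LTBP2, which binds microfibrils, rose by 1.68, the actin-associated TAGLN and MYL9 by 1.48 and 1.38, NPNT by 1.38 and FN1, which encodes fibronectin, by 1.36. XDH, which encodes xanthine dehydrogenase, rose by 1.59, GPR183 by 1.38 and C8orf4 by 1.33.

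The largest falls were of C2orf54 (7.83 ± 4.63 to 0.987 ± 0.05 RPKM, SD, n = 4 each; log2 change -1.99 ± 0.34, adjusted p = 0.0134) and FBP1, which encodes the gluconeogenic enzyme fructose-1,6-bisphosphatase (-1.89). RMRP, the RNA component of the RNase MRP complex, fell by 1.53, HPDL by 1.19, PADI3 by 1.17, C1orf53 by 1.15 and DKK1, which encodes a secreted Wnt antagonist, by 1.10. RMRP went from 12.3 ± 2.75 to 3.77 ± 1.71 RPKM, with 5.92 and 1.77 RPKM in the libraries of guide 2. It had no entry in the annotation used for gene type. C1orf53 was low throughout, at 1.87 ± 0.32 and 0.333 ± 0.39 RPKM, and was listed at 0 in both libraries of guide 1. These values rest on low levels and are uncertain. BAIAP2L2 fell by 1.00, the DNA repair gene NTHL1 by 0.92 and ZNF551 by 0.87. ANKRD10-IT1 fell by 1.38, but it lies within another gene, and without a stated strand setting their reads cannot be told apart.

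In all, 727 of the 13979 genes tested were called between the e3 guides and the controls, 367 higher and 360 lower, and 61 of them differed at least 2-fold (limma, Benjamini-Hochberg adjustment). In 720 of them the e3 libraries all lay on one side of the control libraries, which held for 15.1% of tested genes. Chance gives 2.86% if single libraries vary independently, and up to 1 in 3 if the groups are the units. With the mean of the 2 libraries of each group as 1 sample, 1 gene, IGFBP3, was called, 1525 genes had an unadjusted p under 0.05, and MYC had an adjusted p of 0.407. With an estimated correlation between libraries of a group 256 genes were called, and the count fell to 428 and 425 without the first and second no-guide library, 401 and 386 without those of guide 1, and 186 and 224 without those of guide 2.

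The named changes were not equally large against each control. Against the non-targeting guide alone, MYC fell by 1.16 (adjusted p = 0.00231), IGFBP3 rose by 2.02 (adjusted p = 3.96e-05), ITGB6 by 1.27 (adjusted p = 0.00682), PMEPA1 by 1.10 (adjusted p = 0.0266), LTBP2 by 0.87 (adjusted p = 0.0342), XDH by 0.78 (adjusted p = 0.0204) and FN1 by 0.75 (adjusted p = 0.016), while C2orf54 fell by 1.30 (adjusted p = 0.00931) and FBP1 fell by 0.99 (adjusted p = 0.0256). TAGLN, C8orf4, ANKRD10-IT1, C1orf53, DKK1, BAIAP2L2 and ZNF551 did not pass in that comparison (log2 changes 1.05, 0.73, -0.84, -1.07, -0.58, -0.65 and -0.81). There 956 genes were called, 461 higher and 495 lower, and 485 of the 727 were among them in the same direction. Against the cells without a guide 2336 genes were called.

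Most cytosolic ribosomal protein genes fell with the e3 guides. Of 78 tested, 66 fell and 12 did not pass, and 72 fell when adjusted over the list alone. RPL35A fell by 0.44 (189.4 ± 2.65 to 139.0 ± 1.60 RPKM, SD, n = 4 each), RPL12 by 0.44, RPL18 by 0.43 and RPL10A by 0.41. The median change was -0.35 (camera adjusted p = 1.18e-46, and adjusted p = 0.15 with an estimated correlation). Many ribosomal protein genes have processed pseudogenes that can share their reads, so their single values are uncertain. Of 44 genes for translation factors and tRNA synthetases, 8 fell and 36 did not pass, and 25 fell when adjusted over the list alone. They included EEF1A1 (-0.36), EEF1B2 (-0.41), EIF3E (-0.40) and EIF4B (-0.41), and the list's median change was -0.20 (camera adjusted p = 3.94e-12, and adjusted p = 0.163 with an estimated correlation).

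Of 63 genes listed as MYC targets in the nucleolus and in growth, 15 fell, 1 rose and 47 did not pass, with 33 lower and 1 higher when adjusted over the list alone. The nucleolar FBL fell by 0.31, the mitochondrial chaperone HSPD1 by 0.45, TBRG4 by 0.39 and the sorbitol dehydrogenase gene SORD by 0.57. The median was -0.27 (camera adjusted p = 1.77e-13, and adjusted p = 0.15 with an estimated correlation), and it was -0.39 against the non-targeting guide alone (camera adjusted p = 4.68e-21) and -0.18 against no guide alone (camera adjusted p = 7.89e-05). Of 26 genes for nucleotide synthesis 5 fell, also when adjusted over the list alone, among them PPAT (-0.53) and GART (-0.46) of purine synthesis, SHMT2 (-0.37) and IMPDH2 (-0.34) (camera adjusted p = 0.00241, adjusted p = 0.226 with an estimated correlation, and 0.142 against no guide alone). Of 31 subunits and factors of RNA polymerases I and III 3 fell, POLR1B (-0.49), POLR1E (-0.53) and GTF3C2 (-0.35), and 5 when adjusted over the list alone. GTF3C4 did not pass (-0.32). That list stayed lower with an estimated correlation (adjusted p = 0.0463; with the preset one 8.96e-05).

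Of 21 genes listed as repressed by MYC, 5 rose and 16 did not pass, and 9 rose when adjusted over the list alone. TXNIP, an inhibitor of glucose uptake, rose by 0.69 (124.6 ± 14.8 to 200.6 ± 9.26 RPKM, SD, n = 4 each), the receptor phosphatase gene PTPRK by 0.74, the matrix gene TGFBI by 1.07 and CTGF by 0.39. The list was higher with the preset correlation (camera adjusted p = 0.000203) and with an estimated one (adjusted p = 0.0463). It shares TGFBI, CTGF, VIM and THBS1 with the list of the mesenchymal side of the epithelial-mesenchymal transition, so these lists are not separate evidence. In the MYC network of 10 tested dimerization partners and antagonists, MYC alone was called. MXI1, MGA and MLXIP did not pass, with changes of -0.52, -0.40 and 0.18, and adjusted over the list alone 2 genes were lower (camera adjusted p = 0.0482, adjusted p = 0.191 with an estimated correlation, and 0.179 against the non-targeting guide alone).

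Of 51 genes of the G2 and M phases, 6 fell and 45 did not pass, with 22 lower when adjusted over the list alone. The mitotic genes CDC20 (-0.33), AURKA (-0.32) and NCAPD2 (-0.29) and the proliferation marker MKI67 (-0.28) fell (camera adjusted p = 2.14e-10, and adjusted p = 0.163 with an estimated correlation). Of 41 S phase genes none passed in limma, nor when adjusted over the list alone, and 4 had an unadjusted p under 0.05. RRM1, WDR76, UBR7 and CLSPN had changes of 0.16, 0.32, 0.28 and 0.22, and the list ranked slightly higher than other genes (median 0.09, camera adjusted p = 0.038, adjusted p = 0.418 with an estimated correlation, and 0.495 against no guide alone).

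Of 21 genes of the mesenchymal side of the epithelial-mesenchymal transition, 9 rose and 12 did not pass, and adjusted over the list alone 16 were higher and 1 was lower. The matricellular gene CYR61 rose from 126.4 ± 20.4 to 226.6 ± 23.6 RPKM (SD, n = 4 each; log2 change 0.85), TGFBI by 1.07, the matrix gene SPARC by 1.05 and the transcription factor gene SNAI2 by 0.99. The median was 0.99 (camera adjusted p = 1.15e-09, and adjusted p = 0.194 with an estimated correlation). The same list was also higher with the non-targeting guide than without a guide, with a median of 0.80, and its median against the non-targeting guide alone was 0.55 (camera adjusted p = 2.6e-08). Of 26 epithelial junction and keratin genes, CDH1, which encodes E-cadherin, rose by 0.23, ESRP2 and RAB25 fell by 0.65 and 0.23, and 23 did not pass, among them CLDN3 (-1.74). When adjusted over the list alone 1 gene was higher and 4 were lower, and the list as a whole did not stand apart (camera adjusted p = 0.497). It was lower against no guide alone (camera adjusted p = 0.00344) and higher against the non-targeting guide alone (camera adjusted p = 0.0464).

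Of 22 genes of NF-kB signalling and inflammation, 1 rose, CSF1 (log2 change 1.32, adjusted p = 0.0152), and 2 when adjusted over the list alone. PTGS2, BIRC3 and IL1A did not pass, with changes of 0.75, 1.45 and 1.10. The list's median of 1.01 (camera adjusted p = 2.24e-08, and adjusted p = 0.383 with an estimated correlation) stood beside a median of 1.67 for the non-targeting guide against no guide. Against the non-targeting guide alone its median was 0.10 (camera adjusted p = 0.0097). In all, 20 of the 29 lists passed with the preset correlation, 7 higher and 13 lower. With an estimated correlation 3 passed, which were those of RNA polymerases I and III, MYC-repressed genes and mitochondrially encoded genes. The lower count does not come from correlation between genes alone, because that test also has fewer degrees of freedom. For RNA polymerases I and III the estimate was 0.00403, below the preset 0.01, yet the unadjusted camera p rose from 2.78e-05 to 0.00404.

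**Figure D2:**
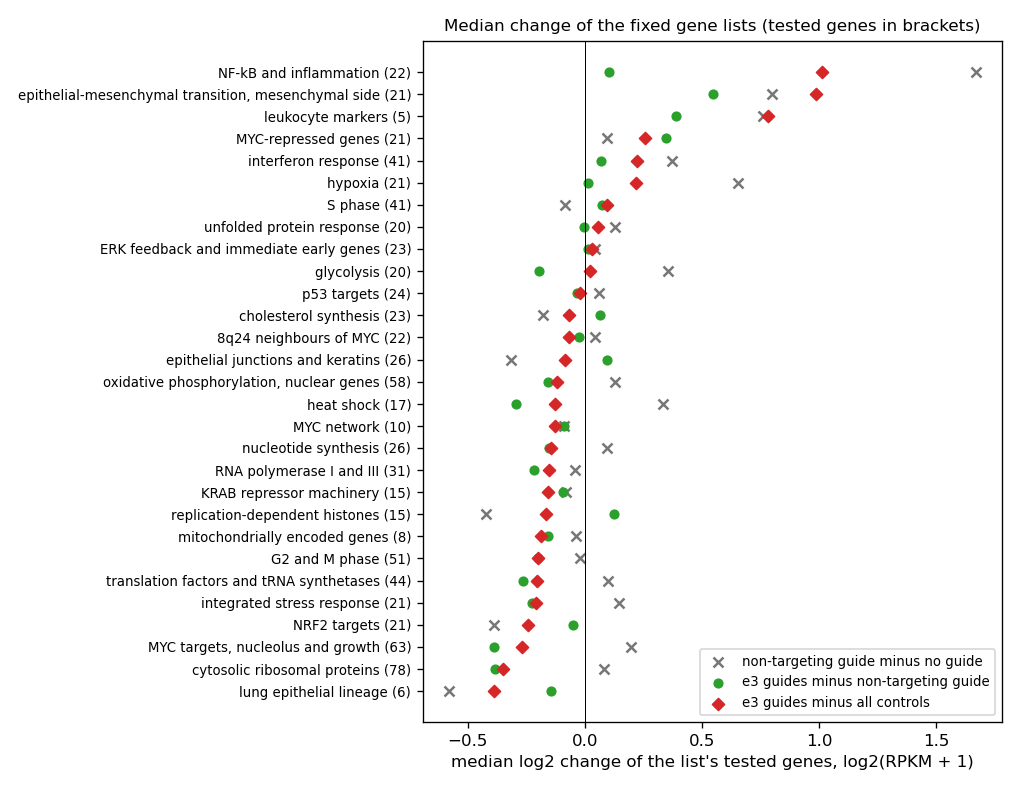
Median log2 change of the tested genes of each of the 29 fixed lists, for the e3 guides against all controls (red), the e3 guides against the non-targeting guide (green) and the non-targeting guide against no guide (grey crosses). The ribosomal protein list had a median of -0.35 against all controls and 0.08 between the controls, whereas the NF-kB list had 1.01 and 1.67.

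Taken singly, guide 1 changed 1257 genes against the controls (694 higher, 563 lower) and guide 2 changed 2022 (957 higher, 1065 lower). The largest rises with both guides included PDZK1IP1, the cytokine gene CSF2 and the chemokine gene IL8, with LCN2 and the acute-phase gene SAA1 for guide 1 and the protease gene MMP9 and CXCL1 for guide 2. The largest falls included the keratin gene KRT4, C2orf54, CLDN3 and FBP1, with WDR89 for guide 1 and PCDH19 for guide 2. PDZK1IP1, for example, changed by 3.42 with guide 1 and by 3.36 with guide 2, but it stood at 0.873 RPKM without a guide and at 107.0 RPKM with the non-targeting guide, beside 150.5 and 143.6 RPKM with the e3 guides. Against the non-targeting guide alone, CSF2 (-0.01), SAA1 (-0.08) and KRT4 (0.32) with guide 1 and PCDH19 (0.17) with guide 2 had changes of the opposite sign that did not pass. SAA1 has a close paralog that can share its reads. WDR89 was low, at 2.16 ± 1.28 RPKM in the controls (SD, n = 4), and was listed at 0 in both libraries of guide 1. With guide 2 it did not pass (-0.26). CLDN3 stood at 3.06 and 0.405 RPKM in the libraries of guide 1, so the sizes of these falls are uncertain.

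Guide 1 and guide 2 called 984 genes in the same direction and 3 in opposite directions, of 1257 and 2022 called. Simulated groups without a guide effect that share controls and differ as the controls do gave 712.0 and 222.9, of 2081 and 2071 called. The totals differ, so these shared counts are not a like comparison. The simulation drew the shift of each group independently, whereas the no-guide libraries lay apart from all others. It therefore does not decide about changes that all groups with a guide share. Across genes, which are not independent replicates, the log2 changes with the guides had a Pearson correlation of 0.683 and a covariance of 0.0800. The guides share their controls: simulated groups without an effect gave a correlation of 0.331 and a covariance of 0.0158, and groups that differed as the controls do gave 0.330 and 0.0636. With split controls the correlation was 0.223 (guide 1 against no guide, guide 2 against the non-targeting guide) and 0.184 (the reverse), with covariances of 0.0348 and 0.0283. There 471 and 365 genes were called in the same direction, where independent lists would share 92.35 and 59.03, and 65 and 54 in opposite directions. Against the non-targeting guide alone guide 1 changed 667 genes and guide 2 changed 1306, and against no guide alone guide 1 changed 1987. Without the first or second library of guide 1 the count for guide 1 was 530 or 461, without those of the non-targeting guide 773 or 759, and without those of guide 2 the count for guide 2 was 962 or 884.

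Compared with each other, the guides differed in 4 genes. Among them, MMP9 was higher with guide 2 (45.8 against 20.5 RPKM; log2 difference 1.12 ± 0.11, adjusted p = 0.0244), and the fatty acid desaturase gene SCD was lower (48.7 against 74.4 RPKM; log2 difference -0.60 ± 0.05, adjusted p = 0.0225). IFITM1 did not pass (log2 difference -1.48, adjusted p = 0.0517). At an unadjusted p under 0.05 there were 1451 genes, where chance gives 698.95. MYC was lower with guide 2 by 0.24 ± 0.05 on the log2 scale, which did not pass (adjusted p = 0.193). Among the 727 genes called for the e3 guides together, the change was larger with guide 2 in 533 (73.3%), and the median ratio of the changes was 1.21. The count of 4 became 24 with a minimum mean of 5 RPKM, 1 without either library of the non-targeting guide, of guide 1 or the second of guide 2, and 0 without the first of guide 2, where 1284 genes had an unadjusted p under 0.05 (limma).

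The controls also differed from each other. The non-targeting guide changed 1728 genes against no guide, 916 higher and 812 lower, and 343 of them at least 2-fold. The cytokine gene CSF2 went from 0.303 to 71.3 RPKM (log2 difference 5.82 ± 0.21, adjusted p = 4.42e-06), CXCL1 from 0.164 to 22.8 RPKM, MMP9 from 0.310 to 24.5 RPKM and PDZK1IP1 from 0.873 to 107.0 RPKM. SAA1 was listed at 0 in both no-guide libraries and at 35.3 and 26.6 RPKM with the non-targeting guide. The keratins KRT4 (39.1 to 0.248 RPKM) and KRT13 (131.6 to 9.13 RPKM), the protocadherin gene PCDH19 (32.6 to 0.936 RPKM) and CYP26A1, which encodes a retinoic acid hydroxylase (7.76 to 0.340 RPKM), fell. PSG1, one of a family of close paralogs that can share reads, fell by 2.65 on the log2 scale. MYC was higher with the non-targeting guide by 0.28 ± 0.05 (adjusted p = 0.0133).

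Of the 29 lists, 18 passed between the controls, and 11 with an estimated correlation. Here that correlation came from the model with 4 groups, whose residuals leave out differences between groups. For the e3 guides it came from the model with 2 groups, whose residuals include the differences between the guides and between the controls. For ribosomal proteins it was 0.013 here and 0.532 there, so the 11 lists and the 3 for the e3 guides are not comparable counts. Genes of NF-kB signalling and inflammation were higher with the non-targeting guide (adjusted p = 0.00879 with an estimated correlation), as were hypoxia genes (median 0.65; adjusted p = 0.0153), glycolysis genes (0.36; adjusted p = 0.0312) and interferon response genes (0.37; adjusted p = 0.0153), and epithelial junction and keratin genes (-0.31; adjusted p = 0.0153) and NRF2 targets (-0.39; adjusted p = 0.0153) were lower, each with an estimated correlation. Leukocyte markers moved with these lists (median 0.76, camera adjusted p = 0.0142, and adjusted p = 0.103 with an estimated correlation), with CD74 higher by 2.64 and HLA-DRA by 1.99. Some lists that were lower with the e3 guides than in the controls were higher with the non-targeting guide than without a guide: ribosomal proteins (median 0.08; adjusted p = 0.0382), translation factors (0.10; adjusted p = 0.0363), oxidative phosphorylation (0.13; adjusted p = 0.034) and heat shock (0.33; adjusted p = 0.0153), each with an estimated correlation. MYC targets ranked higher with the preset correlation (median 0.20, camera adjusted p = 1.59e-05), and the adjusted p was 0.0501 with an estimated correlation. Of the 727 genes called for the e3 guides, 87 were also called here in the same direction and 23 in the opposite one. Independent lists of these sizes would share 44.96 in the same direction. The model with 2 groups counts the difference between the controls as spread, which holds back genes that differ strongly there. The size of this overlap therefore does not show that the changes are separate. The count of 1728 was 990 or 1038 without the first or second no-guide library, and 875 or 870 without those of the non-targeting guide.

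**Figure D3:**
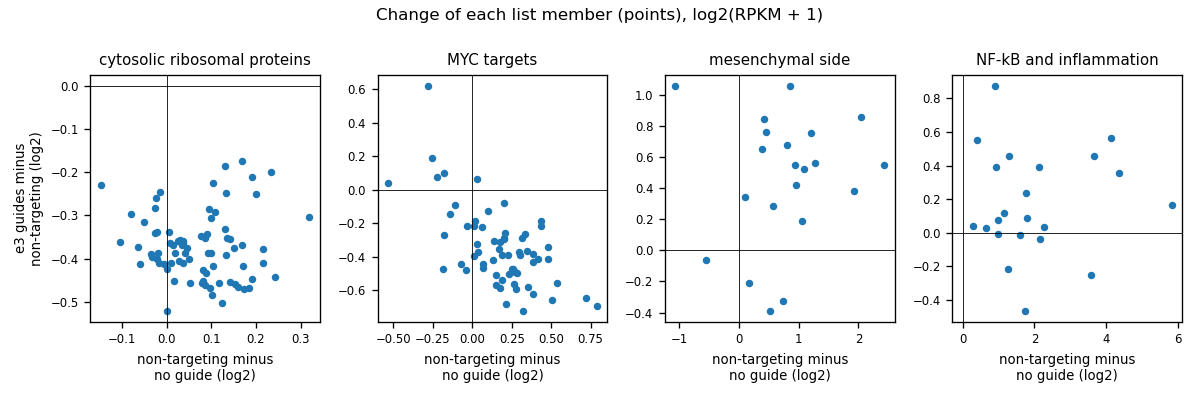
Log2 change of each tested member (points) of 4 lists, with the non-targeting guide against no guide on the horizontal axis and the e3 guides against the non-targeting guide on the vertical axis; each panel has its own axes. Ribosomal protein genes lay below 0 on the vertical axis, with a median of -0.38, while inflammation genes spread along the horizontal axis, with a median of 1.67.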

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

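The removal of the GC and length trend and the thinning to equal depth were chosen after the data had been examined, though before their own results. MMP9 and SCD had different changes with the 2 e3 guides, by a test of the difference itself, though neither passed without a library of either guide or of the non-targeting guide (adjusted p from 0.075 to 0.229), without a variance trend (0.168 and 0.217) or with the replicate block (0.0659), nor MMP9 with a pseudocount of 0.1 (0.0673). The difference of guide 2 minus guide 1 was 1.12 for MMP9 and -0.60 for SCD on the log2 scale. The log2 change was 1.90 with guide 1 and 3.02 with guide 2 for MMP9, and -0.11 and -0.71 for SCD. MMP9 was also higher with the non-targeting guide than without a guide, by 4.28. Groups of 2 libraries were too small to look for single outlying samples.

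Of 35 splits of the libraries into 4 and 4, 1 gave as many as the 727 genes called between the e3 guides and the controls, the real one, and the highest other split gave 2; this had been set to exclude chance, but 32 of the splits part libraries of a group, whose closeness holds their counts low, so it does not decide about chance between groups. A trend in GC content or gene length as the whole cause is argued against by the 87.8% of the calls with an annotated length that were called in the same direction after each library's trend was removed. Differences between separately handled cultures of any kind cannot be told apart from an effect of the guides, since each guide went with its own pair of libraries. The 2 splits that keep each group together and mix e3 with control groups gave at most 1 gene; that bound had been set to count against such differences, but with 3 such splits in all the real one is highest in 1 of 3 by chance, too few for a share under 0.05. Repression of the enhancer, the biological explanation that the design offers, stays open beside that.

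The 1728 genes called between the controls form the second pattern. A GC or length trend as the whole cause is argued against by the 85.2% of calls kept after its removal, and a difference in depth by the 86.4% kept with all libraries thinned to 3875080 reads. What stays open is an effect of a guide without a target, or of its delivery, on these cells, and a difference between cultures unrelated to the guide; the labels give no batch, and no test here separates these.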

How the results depend on the processing

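The alternatives with group means, an estimated correlation within groups and the GC and length trend were chosen after the data were seen. MYC kept its direction in each alternative run, from -1.08 to -0.97 with 1 library left out, and its call in each except group means as samples, where the change was again -1.02 but the adjusted p was 0.407; over the other alternatives the adjusted p ran from 4.37e-06 to 0.0162. That fit has 2 samples per arm, which is its construction, and the unadjusted p for MYC in it was 0.000551 (limma).

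The count of 727 genes for the e3 guides was 406 without a filter, 310 without a variance trend, 2422 in the 4-group model, 2336 against no guide alone, 256 with an estimated correlation within groups, 1 with group means, and between 186 and 581 with 1 library left out. It lay between 682 and 874 with a pseudocount of 0.1, a minimum of 5 RPKM, either scaling, or the GC and length trend removed. The 1257 genes of guide 1 became 564 without a variance trend, 1987 against no guide and 667 against the non-targeting guide, and 461 to 1036 with 1 library left out. The 2022 of guide 2 became 1306 against the non-targeting guide, and 884 to 1839 with 1 left out. The 4 genes between the guides became 9 without a filter, 24 at 5 RPKM, 13 with quantile scaling, 0 without a variance trend (limma, 1307 at an unadjusted p under 0.05), and 0 to 4 with 1 left out. The 1728 between the controls were 870 to 1560 with 1 left out and within 1.5 times otherwise. With a lone library in a group, its spread was assumed to be that of the other groups.

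Of the gene lists 20 passed, 3 with an estimated correlation between genes, 15 without a variance trend and 16 to 19 with 1 library left out. Against no guide alone 20 passed and against the non-targeting guide alone 17, each with 15 of the original 20 among them. The correlation between the guides was 0.599 with a pseudocount of 0.1, 0.595 without a filter and 0.796 at 5 RPKM. Against the non-targeting guide alone CSF2 (-0.014), SAA1 (-0.081), KRT4 (0.318) and PCDH19 (0.167) turned their sign in a single-guide comparison. Of 103 named results past the threshold that could be tested against it, 30 no longer passed and 10 others did. Of 116 or 117 such results, 51 no longer passed without a variance trend, 61 and 58 without the first and second library of guide 2, and 26 to 42 without another library; of 83, 46 no longer passed with an estimated correlation within groups and 82 with group means. The cause of these changes was not tested, apart from the fewer samples or genes that an alternative leaves.

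Replicate numbers did not pair the libraries, as the deviations of same-numbered libraries correlated between -0.022 and 0.014. With the replicate block 387 genes were called for the e3 guides and 1 between the guides, and the other counts stayed within 1.5 times. Scaling moved the median change of all genes from -0.020 to at most -0.007. Depth limits low genes most, since 1 RPKM is 12 to 17.8 reads in a gene of the median length.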

Other observations

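The TGF-beta list, its test without shared genes and the mesenchymal list's comparison with the non-targeting guide were chosen after the leading genes had been seen. Of 21 genes of the integrated stress response 4 fell: the amino acid transporter genes SLC7A5 (-0.70, adjusted p = 0.000583) and SLC3A2 (-0.30) and the serine synthesis genes PSAT1 (-0.42) and PSPH (-0.57); adjusted over the list alone 3 were higher and 9 lower (camera adjusted p = 0.038, adjusted p = 0.253 with an estimated correlation, and 0.579 against no guide alone). Of 58 nuclear genes of oxidative phosphorylation 3 fell, ATP5B (-0.31), NDUFA10 (-0.33) and COX7C (-0.30), and 7 when adjusted over the list alone; NDUFV2 did not pass (camera adjusted p = 2.79e-05, adjusted p = 0.333 with an estimated correlation, and 0.151 against no guide alone). Of 8 mitochondrially encoded genes MT-ND1 (-0.20), MT-ND2 (-0.20) and MT-ND3 (-0.39) fell, 6 when adjusted over the list alone, and MT-ND5 did not pass (-0.16; camera adjusted p = 4.27e-05, and adjusted p = 0.0463 with an estimated correlation); nuclear copies can share their reads. Of 20 glycolysis genes LDHB and PFKM fell by 0.44 each, also when adjusted over the list alone, and SLC2A1 and SLC16A3 did not pass; the list as a whole did not stand apart (median 0.02, mean -0.01, camera adjusted p = 0.751), but it was higher against no guide alone (camera adjusted p = 0.00222) and lower against the non-targeting guide alone (2.37e-05). Of 17 heat shock genes HSPD1 and AHSA1 (-0.36) fell, also when adjusted over the list alone, and HSPE1 and HSPA4L did not pass (camera adjusted p = 0.038, and adjusted p = 0.585 with an estimated correlation). That list ranked lower against the non-targeting guide alone (camera adjusted p = 4.41e-10), while against no guide alone its direction was higher and did not pass (0.412).

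VEGFA (1.29, adjusted p = 0.0242) and PFKFB3 (0.66) rose among 21 hypoxia genes, and P4HA2 and ANGPTL4 did not pass; adjusted over the list alone 6 were higher and 1 was lower (camera adjusted p = 0.000387, and adjusted p = 0.428 with an estimated correlation). The hypoxia list did not pass against the non-targeting guide alone (camera adjusted p = 0.421; median 0.01, beside 0.65 between the controls). SAMD9L (0.87) and IFI35 (0.63) rose among 41 interferon response genes, and TAP1 did not pass; adjusted over the list alone 5 were higher (camera adjusted p = 0.000228, and adjusted p = 0.495 with an estimated correlation). The interferon list did not pass against the non-targeting guide alone either (camera adjusted p = 0.364; median 0.07, beside 0.37 between the controls). Against both controls it was higher with guide 1 (median 0.35, camera adjusted p = 8.94e-12) and did not pass with guide 2 (median 0.11, camera adjusted p = 0.167). ABCC3 (0.55) rose among 21 NRF2 targets, of which 1 was higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0491, lower as a list, adjusted p = 0.585 with an estimated correlation, and 0.738 and higher against the non-targeting guide alone). PLK2 (0.56), PHLDA3 (0.50) and TP53I3 (0.69) rose among 24 p53 targets (5 when adjusted over the list alone), SYVN1 (0.31) among 20 genes of the unfolded protein response (1 when adjusted over the list alone) and the phosphatase gene DUSP4 (0.52) among 23 genes of ERK feedback, where MYC fell (4 higher and 2 lower when adjusted over the list alone). These 3 lists did not pass (camera adjusted p = 0.385, 0.162 and 0.518), and for p53 targets the median of -0.02 and the mean of 0.07 differed in sign. Against no guide alone the unfolded protein response list was higher (camera adjusted p = 0.0133). None of the lists for cholesterol synthesis, lung epithelial lineage and replication-dependent histones passed (camera adjusted p = 0.518, 0.141 and 0.28), and limma called no gene in them, where 3, 4 and 2 genes had an unadjusted p under 0.05; of 6 lineage genes 1 was higher and 3 were lower when adjusted over the list alone. Against no guide alone the lineage and histone lists were lower (camera adjusted p = 0.0125 and 0.0176). The KRAB repressor machinery had no called gene among 15 in limma (5 with an unadjusted p under 0.05) and ranked lower (median -0.16, camera adjusted p = 0.0113, adjusted p = 0.191 with an estimated correlation, and 0.113 against the non-targeting guide alone). Markers of other cell types were mostly too low to test. Of 5 leukocyte markers tested CD68 rose (0.78), with 3 higher when adjusted over the list alone, and CD74, HLA-DRA and CSF1R did not pass (1.62, 1.13 and 0.61; camera adjusted p = 0.00879, and adjusted p = 0.191 with an estimated correlation). CD74 and HLA-DRA differed between the controls by 2.64 and 1.99. UCHL1 fell by 0.40 and ENO2 did not pass as the 2 neuroendocrine markers tested. COL1A1, the 1 fibroblast marker tested, stood at 4.55 ± 1.00 and 6.26 ± 0.50 RPKM (SD, n = 4 each) and did not pass.

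The rise of the mesenchymal list with the e3 guides is the third pattern. Reads from fibroblasts as its source are argued against by the summed rise of COL1A1, COL1A2, COL3A1, DCN and LUM, which was 2.90% of the rise of FN1 by 72.3 RPKM, with COL3A1, DCN and LUM listed at 0. An effect of equal size from any guide RNA may account for part of it, since the change against the non-targeting guide minus that between the controls had a median of -0.39 ± 0.23 (standard error over 21 members). That explanation alone puts the rise over the non-targeting guide at 0, where the median was 0.55 ± 0.11. This error is also over members, which are not independent replicates, and each group was a single pair of libraries. The comparison therefore cannot tell a further effect of the e3 guides from a difference between cultures. A hypothesis is that genes responding to TGF-beta rise together: of 36 tested from a list of 48, 12 rose, 22 when adjusted over the list alone, with p = 0.0172 in camera with an estimated correlation and p = 0.014 without the genes shared with the mesenchymal list, among them ADAM19 (0.81), ITGAV (0.91), BMP1 (0.86) and TPM1 (0.78). The list shares 9 genes with the mesenchymal list, without which 9 of 27 rose (13 when adjusted over the list alone), and was also higher between the controls (median 0.44), so a difference between cultures stays open.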
